A study of Homo sapiens with 2 samples.

How the data were processed

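Total RNA of 2 K562 cultures was measured, 1 array with a control mimic and 1 with a miR-34a mimic, each 24 hours after nucleofection of 3 µg of mimic. Per the labels' protocols, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 15 µg of total RNA by Affymetrix's standard method. The authors deposited 1 table of probe set intensity values for both arrays, on a linear scale in arbitrary units. Its lowest value was 1, which 3.58% of control and 3.54% of miR-34a probe sets held, so the values had a floor. The software, the background correction and the scaling behind the deposited intensity values are not given in the sources used here, and the table has no detection calls. A floor and an unknown background correction affect dim probe sets most. The columns carried the samples' own names, and 0 columns belonged to other samples.

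From the deposited values, log2(intensity + 14.9) was computed, the pseudocount being the 25th percentile of all values. The log2 ratio of a gene is the miR-34a value less the control value on this scale, which understates the change of dim genes. The median ratio over expressed genes, 0.0090, was subtracted. A probe set counted as expressed if its mean log2 level over both arrays was at or above the median of the 54613 probe sets other than controls, which is a signal of about 39.0. The platform's probe annotation gave 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721, and only the first kind was used for genes. Of the probe sets with 1 symbol in that annotation, 99.9% had a gene ID present in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. A gene took the value of its brightest expressed probe set, and the SD over its expressed probe sets was used as technical spread. There were 12774 expressed genes, 5494 of them with 2 or more expressed probe sets. Signals printed in the text are the deposited values of the brightest probe set. No genome position is given, because no build is tied to the probe sets here. A signal at or below the highest of 27 bacterial probe sets of low signal (dap, lys, phe, thr and trp) is called within background. That highest signal, 75.4, lies above the filter, so the expressed genes include genes within background. It was exceeded by 35.1% of probe sets other than controls on the control array and 35.5% on the miR-34a array.

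With 1 array per group no test between groups was possible, so genes were counted by size, at 2-fold. The 22 gene lists, the settings and the rule for named genes were fixed before the data were examined. For each list the median log2 ratio of its expressed members was set against 10000 random lists of the same size, drawn within 20 bins of mean expression. The percentile describes these arrays and is not a p-value. Members of a list are often regulated together, which the random lists do not copy. Some list members were under the filter, shared probe sets with other genes or were not analysed here. The genes named are the 12 largest increases and 12 largest decreases among genes with 2 or more expressed probe sets that all moved the same way, the 3 largest each way among genes with 1, the 2 highest and 2 lowest of each list, and MYB, CDK4, CDK6, CCND1, CCNE2, BCL2, SIRT1, MAP2K1, NOTCH1, ITGA2B, ITGB3, GATA1 and HBG1 where measured. One further gene of that rule is not reported here. A comparison of genes with and without a match to the miR-34a seed in the 3′ UTR had been planned and was not run, since no UTR sequences were used here. The unit turned out as linear intensity, as one branch of the plan had foreseen.

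Alternatives changed the pseudocount, the filter, the centring, the normalization (quantile, or loess with a span of 0.3), the probe sets used per gene and the size threshold. The calculation was tested on simulated data made from the control array with noise of SD 0.3 (log2) and 12778 expressed genes. The genes to be changed were drawn only from expressed genes above the 25th percentile of mean level. Their rates of recovery therefore do not cover the dimmest expressed genes. All of 50 genes raised 4-fold and 98.0% of 49 genes lowered 4-fold were past 2-fold. Of genes changed by 2-fold exactly, 40% of 50 in each direction were, and of 12549 unchanged genes 0.0080%. The simulated noise had the same SD at every signal level, so the last rate cannot be carried over to genes within background. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.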

Results

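Messenger RNA levels were measured on Affymetrix expression arrays in K562 cells, a human erythroleukemia line grown in suspension culture. One culture had received 3 µg of a synthetic mimic of the microRNA miR-34a by nucleofection (electrical transfer of nucleic acid into the nucleus and cytoplasm), and the other the same amount of a control mimic. Total RNA was taken 24 hours later. The series therefore held 1 array per group, and every value below is a single measurement without a replicate. A size of change is given for each gene, no p-value could be computed across cultures, and the number of arrays limits the precision. The array has 54675 probe sets, with a median signal of 39.5 on the control array and 40.1 on the miR-34a array. Background was read from 27 probe sets for bacterial transcripts at low signal, which had medians of 11.5 and 10.4 and a highest value of 75.4. The 18 probe sets for spiked-in control RNA had a mean log2 ratio of 0.014 ± 0.069 (SD over probe sets), so the scales of the arrays lay close together. The 3′ to 5′ signal ratio, a measure of RNA integrity that grows with degradation, was 3.07 for GAPDH on the control array and 3.53 on the miR-34a array, and 4.30 and 4.54 for ACTB.

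The first comparison asked which mRNAs differed in level between cells with the miR-34a mimic and cells with the control mimic. Of 12774 expressed genes, 76 were at least 2-fold higher and 70 at least 2-fold lower with miR-34a, together 1.14% of the genes, and 93.7% of genes lay within 1.5-fold. These counts depend on how dim genes are treated: they were 28 and 41 with 4 times the pseudocount and 215 and 206 with no filter on expression. The largest decreases shared by all expressed probe sets of a gene included the cell cycle kinase CDK6, the Notch-induced repressor HES1 and the Wnt pathway transcription factor LEF1. The largest increases of that kind included TUBB1, the tubulin of platelets and megakaryocytes, RHD, the Rh blood group antigen of red cells, and the immediate-early transcription factor EGR1. Mature miR-34a is not measured by this array, and the probe set named for its gene, MIR34A, read 57.2 and 59.8, both within background. That probe set does not detect a transfected mimic and checks nothing about the labels.

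Among the 12 genes with the largest decrease over 2 or more agreeing probe sets, TSEN15, a subunit of the tRNA splicing endonuclease, went from a signal of 576.6 to 146.9, a log2 ratio of -1.88 with an SD of 0.66 over its 3 probe sets. PPP1R11, an inhibitor of protein phosphatase 1, stood at -1.74 ± 0.22 (SD, 2 probe sets). HES1 had a log2 ratio of -1.72, with signals of 211.3 and 53.9, the latter within background. The apolipoprotein gene APOC1 had -1.66 ± 0.23 (SD, 2 probe sets). HMGN4, which encodes a nucleosome-binding protein, had -1.53 with an SD of 0.070 over 3 probe sets. The nucleoside transporter SLC29A1 had -1.44 and LEF1 -1.33, with SDs of 0.20 and 0.093. GINS3, a subunit of the replicative helicase complex, was at -1.26 on its brightest probe set and -1.28 on the other. The probe sets of some of these genes disagreed in size. CDK6 lay between -1.70 and -0.087 over 5 probe sets, and the nuclear pore gene NUP210 between -1.70 and -0.11 over 5. Apart from the probe set with the smallest change, CDK6 lay between -1.70 and -0.99 and NUP210 between -1.70 and -1.45. The TFIID subunit gene TAF4B lay between -1.62 and -0.023, and ARPP19, which encodes an inhibitor of protein phosphatase 2A, between -1.51 and -0.012. The second probe set of TAF4B was at almost no change, and so were both other probe sets of ARPP19, at -0.059 and -0.012.

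Among the 12 largest increases over agreeing probe sets, TSPAN32, a tetraspanin gene, had a log2 ratio of 1.95, from a control signal of 41.9 that lay within background to 205.5. The acyl-CoA synthetase gene ACSM3 had 1.63 ± 0.18 (SD, 2 probe sets), with signals of 174.0 and 575.3. TUBB1 had 1.62, with its second probe set at 0.44, and RHD had 1.61 with an SD of 0.27 over 3 probe sets. Probe sets shared by RHD and its near-identical neighbour RHCE gave 1.64 and 1.54, and the array does not separate the pair with certainty. NNMT, the nicotinamide N-methyltransferase gene, had 1.59, ARHGAP25 1.39, and AIF1, a gene of macrophages, 1.44 from a control signal of 34.9 within background. DPCD and DYNC2LI1, both linked to cilia, had 1.38 and 1.24. ABHD5, a coactivator of fat breakdown, had 1.25 and EGR1 1.23 ± 0.24 (SD, 3 probe sets). The pseudogene FAHD2CP had 1.20 from a control signal of 26.9 within background, with a second probe set at 0.11 that read within background on both arrays. Of genes with a single expressed probe set, NRK, a protein kinase gene, had the largest increase at 2.34, followed by C11orf21 at 2.22 and ALAS2, the first enzyme of heme synthesis in red cell precursors, at 1.88. Their control signals of 26.2, 74.0 and 24.6 lay within background. C11orf21 and TSPAN32 overlap in the RefSeq gene table, and whether their probe sets read separate transcripts was not tested. The largest decreases of that kind were NAGPA, an enzyme of lysosomal protein sorting, at -1.91, LOC100996549 at -1.85, and SGPP1, a sphingosine phosphate phosphatase, at -1.70, each with a miR-34a signal within background.

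Other probe sets of the same gene were the internal check on these sizes. Of the 26 genes at least 2-fold higher that had a second expressed probe set, 25 moved the same way on it, and so did 23 of the 28 that were at least 2-fold lower. Over all 5494 genes with 2 or more expressed probe sets, the first and second moved the same way in 66.0%. Their spread about a shared value was 0.22 on the log2 scale, which covers differences between probe sets on these arrays and not differences between cultures. In 36 of the 76 higher genes the control signal lay within background, and in 22 of the 70 lower genes the miR-34a signal did. The log2 ratios of such genes rest on a dim measurement.

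**Figure D1:**
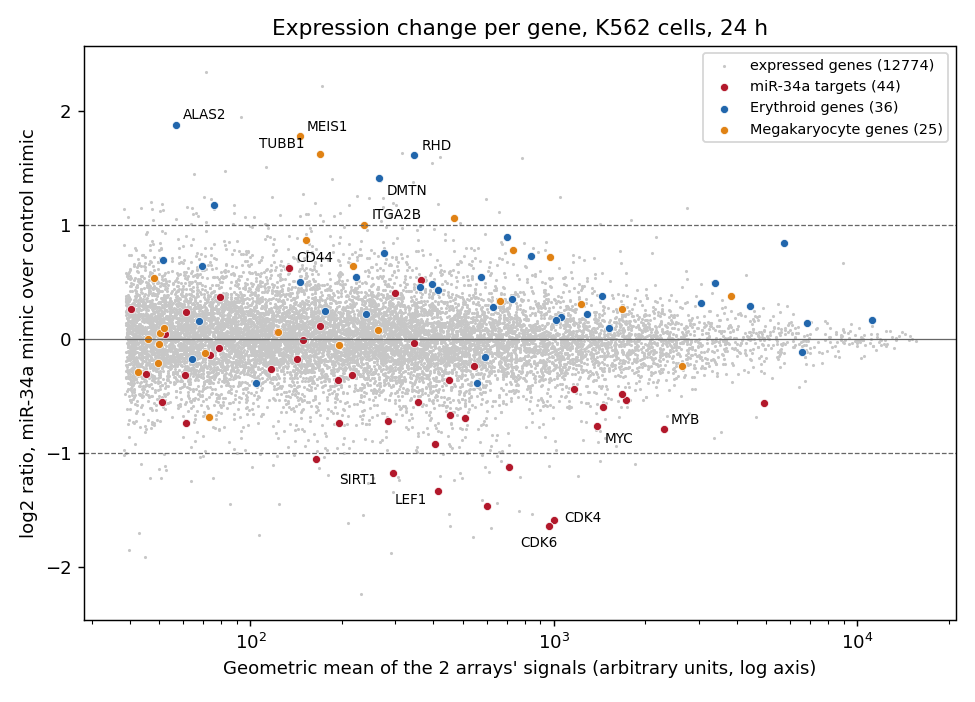
Each point is 1 of 12774 expressed genes, with the geometric mean of the arrays' signals on a log axis (arbitrary units) against the log2 ratio of miR-34a mimic over control mimic, and dashed lines at 2-fold. Of the coloured lists, 35 of 44 miR-34a targets lie below 0, and 31 of 36 erythroid and 18 of 25 megakaryocyte genes lie above it.

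The next comparison asked whether genes known as direct targets of miR-34a were lower with the mimic. They were lower as a group. Of the 56 targets listed in advance, 44 were expressed, 35 of these were lower and 9 higher, and 7 were at least 2-fold lower while 0 were at least 2-fold higher. The median log2 ratio was -0.40, below the medians of all 10000 random lists matched for size and expression, whose SD was 0.044. The kinases that drive cells from G1 into S phase had the lowest values. CDK6 went from 1713.8 to 543.2, a log2 ratio of -1.64, and CDK4 from 1743.4 to 572.8, at -1.59 on its single probe set. SIRT1, a protein deacetylase gene, had -1.17, the kinase gene MAP2K1 (MEK1) -0.93, and MYB, a transcription factor of blood progenitors, -0.79 with a second, dim probe set at -0.56. NOTCH1 stood at -0.56 and the cyclin gene CCNE2 at -0.32. Some listed targets did not go this way. CD44, an adhesion receptor gene, had 0.63 and was higher on 5 of 6 probe sets, and the cyclin gene CCND1 had 0.51. The 4 probe sets of the survival gene BCL2 read at most 28.1 on either array and stayed under the filter. These percentiles describe this pair of arrays and carry no error between cultures.

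Mitosis genes and MYC target genes were lower as lists, while the medians of the DNA replication and G1/S lists lay within the range of random lists. All 41 listed mitosis genes were expressed, 37 were lower, and 0 passed 2-fold. Their median log2 ratio was -0.18, at the 0.020th percentile of random lists, with the kinetochore gene SPC25 at -0.78 and the spindle gene HMMR at -0.73 as the lowest and ANLN at 0.36 and INCENP at 0.27 as the highest. Of 27 expressed MYC target genes, most of which act in ribosome production, 23 were lower, with a median of -0.23 that lay below all random lists. CDK4 and the ribosome assembly gene RRP9, at -0.59, were the lowest, and EIF4E at 0.092 and RRP12 at 0.084 the highest, although another probe set of RRP12 gave -0.24. MYC itself went from 1813.7 to 1066.2, a log2 ratio of -0.77. Of 48 DNA replication genes, 30 were lower, with GINS3 and MCM3, at -1.26 and -1.20, past 2-fold, and CLSPN at 0.54 and POLA2 at 0.18 as the highest. The control signal of CLSPN lay within background, and its other probe set gave -0.082. The median of this list was -0.069, at the 8.46th percentile, and it moved to -0.14, at the 0.080th percentile, when all expressed probe sets of a gene were averaged. Of 21 genes for G1/S cyclins, kinases and their regulators, 13 were lower, and the median was -0.067, at the 19.7th percentile. CDK6 and CDK4 were its only members past 2-fold, while TFDP2, a partner of E2F factors, had 0.53 and CCND1 0.51. The value of TFDP2 was -0.075 as a mean over its probe sets and -0.60 without the less specific probe set classes.

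Genes of the erythroid and megakaryocyte lineages, the directions in which K562 cells can mature, were higher with miR-34a. Of 36 expressed erythroid genes, 31 were higher, 4 of them at least 2-fold, and 0 were 2-fold lower. The median log2 ratio was 0.37, above all 10000 random lists. ALAS2 and RHD were the highest, at 1.88 and 1.61, and TRIM58 and SLC25A38 the lowest, at -0.39 and -0.38. The control signal of ALAS2, 24.6, lay within background. The erythroid transcription factor gene GATA1 had 0.22 and 0.23 on its probe sets. The 6 probe sets shared by the alpha globin genes HBA1 and HBA2 read 5977 to 8183 on the control array and gave log2 ratios between 0.28 and 0.45. The 3 probe sets shared by the gamma globin genes HBG1 and HBG2 gave -0.044 to -0.0067, at signals of 12262 to 15162, close to the highest signal of that array, 15627. Of 25 expressed megakaryocyte genes, 18 were higher and 7 lower, and 3 were at least 2-fold higher. These counts include genes that read within background on both arrays. They were ITGB3, PLEK, LAT and CD36 among the higher and GP9, PF4, GP1BA and SELP among the lower. A further 9 listed genes, PPBP and GP5 among them, were under the filter. Their median was 0.26, at the 99.99th percentile. MEIS1, a homeobox gene of megakaryocyte progenitors, had 1.78 from a control signal of 73.1 within background, and TUBB1 had 1.62. ITGA2B, which encodes the platelet integrin subunit CD41, went from 163.4 to 344.0. This was a ratio of 2.10 in signal and just short of 2-fold after the pseudocount and the centring. The second probe set of ITGA2B gave a log2 ratio of 1.56 from a control signal of 34.7 within background. Its partner ITGB3 read 37.5 and 61.6, both within background, and no change is read from it. FLI1, a transcription factor of megakaryocytes, had -0.68 on a dim probe set and 0.025 on another, and GP9 had -0.29 within background. The megakaryocyte median was 0.12, at the 97.6th percentile, when genes under the filter were counted too. On the miR-34a array, where both lists were higher, the 3′ to 5′ ratio of GAPDH was 3.53 against 3.07 on the control array.

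Markers of other cell types served as a check on identity and lineage. Only 6 of 22 myeloid and 7 of 18 lymphoid markers were expressed. Among the myeloid ones AIF1 had 1.44 and SPI1, the gene of the transcription factor PU.1, 1.07, both from control signals within background, while CSF3R had -0.22 and CSF1R -0.14, with its miR-34a signal within background. Their median was 0.11, at the 78.3rd percentile, and it turned to -0.020, at the 35.4th percentile, with the filter at the 25th percentile of level and to -0.15, at the 3.76th percentile, without a filter. Among the lymphoid ones the T cell receptor component gene CD3D had -1.41, from 953.6 to 351.9, and CD79B had 0.17. CD4 and MS4A1 read within background on both arrays, and no change is read from them. The list's median was 0.040, at the 62.3rd percentile. Of 10 expressed stromal and epithelial markers, 9 were lower, with EPCAM, an epithelial adhesion gene, at -1.12 and the collagen gene COL1A2 at -0.91, and CLDN7 at -0.0068 and KRT7 at 0.025 as the highest. Their median was -0.32, at the 0.040th percentile. It was -0.12, at the 3.66th percentile, without a filter and -0.22, at the 6.99th percentile, with probe sets of the less specific classes left out.

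The remaining lists had medians between the 2.5th and the 97.5th percentile of random lists, although single members changed by more. Of 23 Notch pathway genes 13 were lower, with a median of -0.080 at the 9.27th percentile. It turned to 0.058, at the 76.2nd percentile, with the filter at the 75th percentile of level, and was -0.17, at the 3.28th percentile, without the _s_at, _x_at and _a_at classes. HES1 was at -1.72 and NRARP, another gene induced by Notch, at -0.95, while MFNG and NCSTN were highest at 0.54 and 0.28. MFNG had a control signal within background and a second probe set at -0.31. In the Wnt list the median was -0.094, at the 8.31st percentile, and 0.0055 with the filter at the 75th percentile of level, with LEF1 at -1.33, ZNRF3 at -0.34, CTNNB1, the beta-catenin gene, at 0.42 and APC at 0.34. The value of APC was -0.51 on its remaining probe set of the more specific class, and the miR-34a signal of ZNRF3 lay within background. Among MAPK and immediate-early genes EGR1 had 1.23 and MAFF 1.09, while FOSL1 had -1.05 and MYC -0.77. The median of that list was -0.045 and its mean 0.10, and the median was 0.064 with that filter and 0.034 without those classes. MAFF was the less certain of these, since its second probe set gave -0.32. The p53 target genes, measured because miR-34a is itself induced by p53, had a median of -0.0095, at the 43.5th percentile, with PERP at -0.57, SESN2 at -0.42, DDB2 at 0.50 and RRM2B at 0.36. PERP on the miR-34a array and DDB2 on the control array were within background. The BCL2 family had a median of 0.066, with BCL2L1 at 0.29, BAK1 at 0.26, PMAIP1 at -0.18 and MCL1 at -0.066. Other probe sets of PMAIP1 and MCL1 went up to 0.29 and 0.31.

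Lists for responses to the transfection itself and for metabolism gave small shifts. Both cultures received a mimic by nucleofection, so a response to transfection that they shared cancels in the ratio and is not measured here. Interferon response genes, which foreign RNA can induce, had a median of -0.055, at the 15.9th percentile, or 0.011 with probe sets averaged, and a mean of 0.079. UBE2L6 had 0.83 and ISG15 0.50, against IFI35 at -0.41 and BST2 at -0.39. UBE2L6 on the control array and IFI35 on the miR-34a array were within background. The amino acid and unfolded protein stress list had -0.088, at the 6.03rd percentile, with XBP1 at -0.98, TRIB3 at -0.60, SLC7A11 at 0.56 and ATF3 at 0.43. The second probe set of XBP1 gave 0.24 and that of ATF3 -0.22. Heat shock genes had a median of -0.034, with DNAJB4 at 0.69, HSPA6 at 0.50 and HSPA9 at -0.32, and CRYAB read within background on both arrays. This list leaves out HSPA1A and HSPA1B, whose 3 shared probe sets, named after their values were seen, gave -1.04, -0.99 and -0.70. Cholesterol synthesis genes had 0.057, at the 91.3rd percentile, with TM7SF2 at 0.98, STARD4 at 0.60, HMGCS1 at -0.56 and DHCR7 at -0.46. Without the _s_at, _x_at and _a_at classes that median was 0.12, at the 97.54th percentile. The control signal of TM7SF2 lay within background, and the second probe set of HMGCS1 gave 0.27. Glycolysis genes had -0.058, with HK2 at -0.66 and LDHA at -0.56 lowest and PDK1 at 0.51 and SLC2A3 at 0.43 highest, although another probe set of PDK1 gave -0.30. Genes of the microRNA machinery had -0.044, with MOV10 at -0.74, DICER1, which cuts microRNA precursors, at -0.63, TNRC6B at 0.71 and AGO4 at 0.68. Another probe set of TNRC6B gave -0.56, and the control signal of AGO4 lay within background. Housekeeping genes had -0.10, at the 4.64th percentile, with TUBB at -0.37, POLR2A at -0.35, ACTB at 0.11 and EEF1A1 at 0.039.

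**Figure D2:**
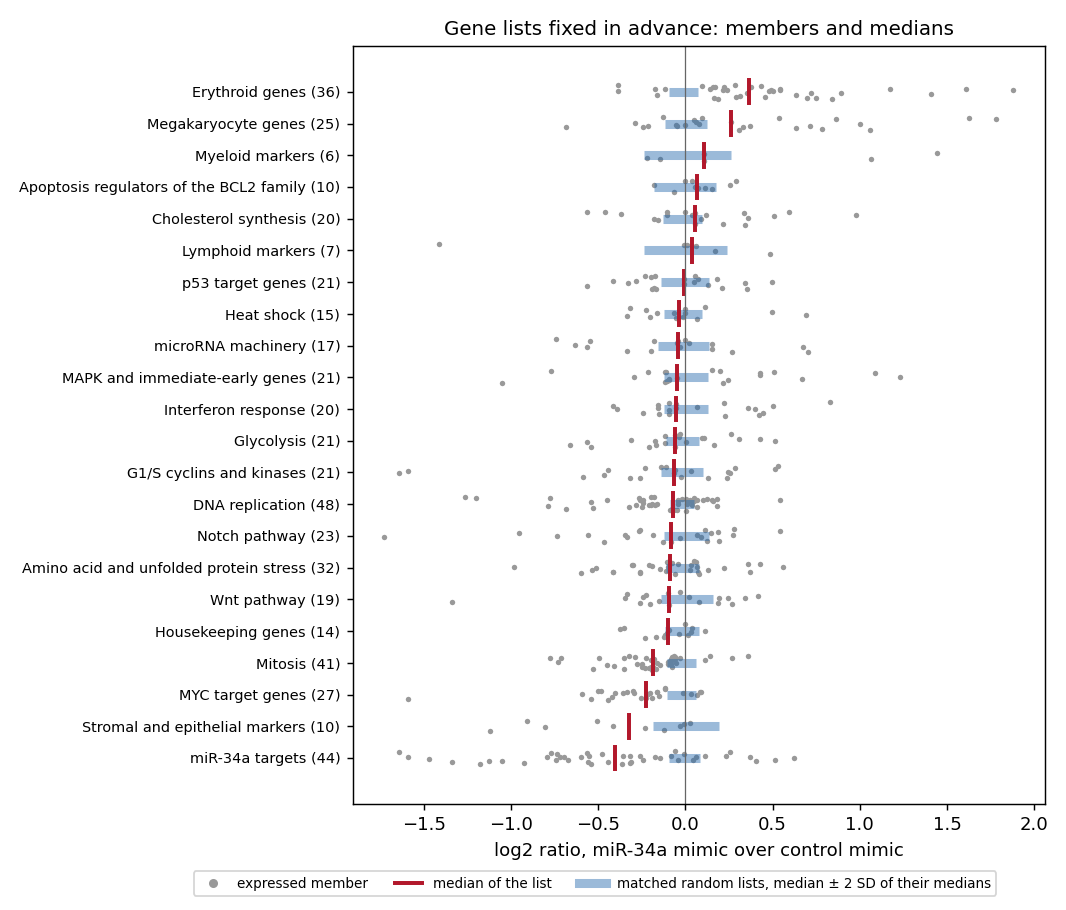
Log2 ratio of miR-34a mimic over control mimic (horizontal axis) for the expressed members of 22 gene lists (rows, with the number of members), as grey points with the list's median as a red bar and the range of matched random lists' medians, their median ± 2 SD, as a blue band. The red bars of the miR-34a targets, stromal and epithelial markers, MYC targets and mitosis genes lie left of their bands, and those of the erythroid and megakaryocyte genes lie right of theirs.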

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

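The tests in this part were chosen after the result was seen, except those of the trend with signal level, which were written down first.

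Signal changes were also present in probe sets outside the gene comparison. Of 4259 expressed probe sets with no gene named, 21 were at least 2-fold higher and 6 at least 2-fold lower with miR-34a. Of 1116 expressed probe sets shared by several genes, 7 were at least 2-fold higher and 8 at least 2-fold lower. Among the latter, named here after their values were seen, a probe set shared by VMP1 and MIR21 had a log2 ratio of -1.73. One shared by the heat shock genes HSPA1A and HSPA1B had -1.04. The 4 probe sets shared by PDE4DIP and a pseudogene that passed 2-fold lay between -1.34 and -1.10, and another of that pair gave -0.82.

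The list of miR-34a targets was lower, with a median log2 ratio of -0.40. Lists of growth and signalling hold 14 of its 44 expressed members, and without these the remaining 30 had a median of -0.34 (SD of random lists 0.055), so overlap with those lists does not account for the whole shift. After removal of a trend of the ratio with signal level the median was -0.39, against a random-list SD of 0.044, which argues against such a trend. The random lists were already matched on mean expression. This check therefore largely repeats that matching, here and for the erythroid and megakaryocyte genes below. A difference between the 2 cultures or their arrays other than the mimic stays open for all lists, since there was 1 array per group. A direct effect of the mimic is consistent with the direction, and remains a hypothesis.

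Erythroid and megakaryocyte genes were higher together, with a joint median of 0.31 over 61 genes. The 49 members with a mean signal above every bacterial background probe set had a median of 0.37, with 42 higher, but ALAS2, SLC4A1 and MEIS1 passed with control signals within background. Noise of dim probe sets would leave bright members near 0, but the 45 members above background on both arrays had a median of 0.35, with 39 higher and a random-list SD of 0.036. After removal of the trend with signal level the joint median was 0.33, with a random-list SD of 0.034. What stays open is a difference between the 2 cultures or their arrays other than the mimic, with 1 array per group. It could lie in density or maturation at transfection, or in RNA integrity, and none of these was tested. The 3′ to 5′ ratios on the control and miR-34a arrays were 3.07 and 3.53 for GAPDH and 4.30 and 4.54 for ACTB. A shift of these cells toward maturation under miR-34a is a candidate explanation that this design cannot separate from such differences.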

How the results depend on the processing

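No list median that lay outside the 2.5th to 97.5th percentile changed sign under any alternative. Of 1063 values of the 113 named genes, 63 moved by more than the probe set spread of 0.22. Of these values 0 reversed from a size past 2-fold, but many of the named genes were under 2-fold and could not be counted so. Many of the others were named because all their probe sets moved the same way, or had 1 probe set, so this 0 says little about them. Values of 8 named genes under 2-fold changed sign in some setting, by more than that spread for APC, ITGB3, TFDP2 and PMAIP1, the last at 0.061 with probe sets averaged. Of 220 recomputed list medians, 194 stayed within 1 SD of random lists' medians. Counts of genes past 2-fold depended most on the settings: higher and lower genes numbered 28 and 41 with 4 times the pseudocount, 136 and 125 with the filter at the 25th percentile, 42 and 46 at the 75th, 215 and 206 with no filter, 419 and 384 at 1.5-fold, and 10 and 12 at 3-fold. With genes held to 2 or more probe sets that all moved the same way, an alternative added after seeing the data, they were 23 and 23. Not centring, 0.5 times the pseudocount, quantile normalization, loess, averaging of probe sets and leaving out probe set classes kept both counts within 1.5 times. The target median was -0.33 with 4 times the pseudocount, -0.55 with the filter at the 75th percentile, -0.35 without probe sets of the _s_at, _x_at and _a_at classes, and -0.34 without members of growth and signalling lists, also added later. Stromal and epithelial markers moved to -0.22 with 4 times the pseudocount, -0.18 and -0.49 with the filter at the 25th and 75th percentile, -0.12 without a filter, -0.21 with probe sets averaged and -0.22 without those classes. With the filter at the 75th percentile the medians were 0.65 for megakaryocyte genes, 0.064 for MAPK, 0.058 for Notch and 0.0055 for Wnt genes. Myeloid markers had -0.020 with the filter at the 25th percentile and -0.15 without a filter, where megakaryocyte genes had 0.12. With probe sets averaged, DNA replication had -0.14, erythroid genes 0.30 and interferon response genes 0.011. Without the _s_at, _x_at and _a_at classes the medians were 0.36 for megakaryocyte, 0.27 for erythroid, 0.034 for MAPK, -0.17 for Notch, 0.12 for cholesterol synthesis and -0.29 for MYC target genes. Fewer or more genes entered under each filter, and the cause of the other moves was not tested. The value of NUP210 was -0.10 and that of ITGB3 -0.18 without those classes. For NUP210 this was the brightest remaining probe set, and another of the more specific class gave -1.45. No replicate could be left out, no paired analysis was possible because each group held 1 array, the settings foreseen for seed sites were not run, and at the 75th percentile filter too few myeloid markers were left for a median. Signals near background limit the dim genes.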

Other observations

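Tests in this part were written down before their values were seen, apart from the ones on cultures and on members above background on both arrays; the theme itself was noticed among the genes with the largest increases. Besides DPCD and DYNC2LI1, several other genes near the top of the increases belong to cilia, the microtubule-based protrusions that most resting cells can form. A list of 114 other cilia genes was therefore written without those seen at the top. Of its 73 expressed members 56 were higher and 17 lower with miR-34a, and the median log2 ratio was 0.19. Genes of intraflagellar transport, which carries cargo along cilia, included IFT22 at 1.11, IFT81 at 0.77 and IFT74 at 0.71, and the motor subunit KIF3B had 0.78 and TTC8, of the BBSome complex, 0.69. TEKT2, TMEM216 and IFT27 had the lowest ratios but read within background on both arrays, and no change is read from them. Of members above background on both arrays, the lowest were ARMC3 at -0.31, CFAP298 at -0.27 and IFT46 at -0.23. These genes were picked by their values after these were seen, and IFT81 had a control signal within background. The second probe set of IFT81 gave -0.040.

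A handful of top-ranked genes alone would leave a list of other cilia genes near 0, but its median of 0.187 lay above all 10000 random lists, whose SD was 0.037. The 56 members with a mean signal above bacterial background had a median of 0.188, with 48 higher, but IFT81, IQCE, BBS12, IFT56, RFX2 and CC2D2A passed with control signals within background. Noise of dim probe sets is argued against by the 50 members above background on both arrays, 42 of which were higher, with a median of 0.185 and a random-list SD of 0.040. The median stayed between 0.14 and 0.21 over 10 alternative settings. A difference between the 2 cultures or their arrays other than the mimic cannot be told apart from an effect of miR-34a, with 1 array per group.

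The overlap of TSPAN32 and C11orf21, both near the top of the increases, raised the question of whether neighbouring genes moved together. Over 11431 pairs of adjacent expressed genes whose spans do not overlap, the correlation of log2 ratios across genes, which are not independent replicates, was 0.016, at the 95.8th percentile of 1000 shuffles of gene order, which ranged from -0.028 to 0.030. The test left out overlapping genes such as this pair, and most of its genes differed little between the arrays. The bound written down for it, a correlation above all 1000 shuffles, was not reached. Given those limits of the test, whether a shared position explains the pair or other large changes stays open.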
